A study of Mus musculus with 21 samples.

How the data were processed

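RNA was measured in 21 libraries of cultured mouse mammary fibroblasts in 7 groups of 3. Per the labels, fibroblasts from normal FVB/n mammary glands (NF) and from MMTV-PyMT mammary carcinomas (CAF) were grown in DMEM with 10% serum and transfected at 60% confluence with 100 nM siRNA by means of DharmaFECT 1. TGFb1 at 5 ng/mL or vehicle was added 5 h later, RNA was taken 48 h after transfection, and stranded mRNA libraries were made with a TruSeq kit. The labels number the replicates of each group as a batch from 1 to 3. Animals, cultures, passage and sequencing runs are not given in the sources used here.

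The authors deposited estimated counts per gene from Salmon, with STAR named beside it and GRCm38 as the genome, and no versions or parameters are given. These expected counts were not normalised, 10.9% of the values were not whole, and they were rounded to whole numbers here, which moved a value by at most 0.5. The authors also deposited TPM values, scaled by transcript length, from the same tools and with the same sum in each library, and these were used only to check the targets. In TPM, Hsp90aa1 with its siRNA was 10.8% of the control in NF and 9.42% in CAF, and 46.7% and 47.7% with siHsp90ab1. Hsp90ab1 with its siRNA was 14.0% and 10.3%, and 87.1% and 80.5% with siHsp90aa1. All columns were mapped to a sample.

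Differences were tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr by group (minimum count 10, minimum total 15), a quasi-likelihood fit of all 21 libraries with 1 coefficient per group, and quasi-likelihood F tests. Each p was adjusted by Benjamini-Hochberg within a comparison, and a gene passed at an adjusted p under 0.05. Of 45706 genes 15230 were tested, and 98.8% of all and 99.5% of tested genes were matched to GENCODE vM21. The standard error of a log2 fold change is its size divided by the square root of F, and the prior count was 0.125. There were 10 contrasts, 8 between groups of 3 and 2 for the difference of a knockdown effect between CAF and NF. Levels are TMM-normalised CPM. Principal components used log2 CPM with a prior count of 2.

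Totals per library, in units of 1e+06 counts, ranged from 41.5 to 59.4 in NF with vehicle, 37.4 to 53.9 with TGFb1, 36.2 to 51.8 with siHsp90aa1, 38.0 to 52.9 with siHsp90ab1, 35.1 to 70.4 in CAF controls, 42.4 to 68.7 with siHsp90aa1 and 40.9 to 47.4 with siHsp90ab1. Pairs of replicates differed by a chi-square per degree of freedom of 17.5 to 155, far above counting noise, and their log2 values correlated at r from 0.982 to 0.992, so the spread between libraries and not depth sets the precision. The fit was tested on simulated data with 200 changed genes per comparison. Changes of 2-fold were recovered in 77.6% to 97.0% of cases, and the highest false share of calls was 8.33%. In camera 8 of 8 shifted lists and 0 of 8 unchanged lists passed at an unadjusted p under 0.05. The simulation drew genes and libraries independently, so it does not test the fit or camera on correlated genes or paired libraries.

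Equal replicate numbers pair the libraries across groups. Over 9340 genes the deviations from the group means correlated for same-numbered libraries in 55 of 63 pairs at r over 0.1, with a mean of 0.347 and a range from -0.104 to 0.914, against a mean of -0.167 for other numbers. The replicate number was left out of the fit by a choice made before the data were examined, and the fit with it as a block is given where it changes the call of a list or moves a count of calls by more than 1.5-fold. It was not run for the counts of TGFb1-changed genes that each knockdown moved back.

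The 19 gene lists, the 5 marker lists, the comparisons, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover HSP90 and its co-chaperones, heat shock factor targets, TGFb signalling targets, contractile genes, matrix, collagen processing, matrix proteases and inhibitors, YAP and SRF targets, cytokines, interferon-stimulated genes, the cell cycle, p53 targets, endoplasmic reticulum chaperones, the integrated stress response, cholesterol synthesis, hypoxia and glycolysis, resting fibroblasts and growth factors. They were tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01, with 152 list tests adjusted together and 40 marker tests adjusted apart. Lists made from genes over 2-fold changed by TGFb1 or between CAF and NF were tested in comparisons that share no library with them. Expected overlaps were computed for independent calls and from 25 simulations of unchanged groups that share a control, with libraries drawn independently.

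Named genes are the HSP90 genes, the 10 largest rises and 10 largest falls of CAF against NF, TGFb1 and each knockdown, the first 5 each way of the other comparisons, and for each list the 4 members with the smallest p. The largest changes needed an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, no overlap between the libraries of both groups (10% by chance for 3 against 3) and a symbol that is not a predicted or clone name. After the data were examined 1 more clone name was left out, so that Mx1 is named in siHsp90aa1 against siHsp90ab1 in NF. Values of 3 genes are not reported here. A gene with no counts in a group is given against a floor of 3 counts over the group, and one with up to 3 counts by its ratio with a 95% exact interval.

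Alternatives were RLE and upper quartile factors, DESeq2 1.42.0, limma voom, no low-count filter, a filter at 1 CPM in 3 libraries, a fit of the compared groups alone, the replicate block, stricter thresholds, an estimated correlation, fry, no fold change minimum for the derived lists, and leaving out each library in turn. Added after the data were examined were leaving out libraries for lists and overlaps, the derived lists in siHsp90aa1 against siHsp90ab1, the overlap of CAF against NF with TGFb1, and list tests of the difference between CAF and NF. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.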

Results

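RNA sequencing was carried out on cultured mouse mammary fibroblasts, with 21 libraries in 7 groups of 3. NF are fibroblasts from the normal mammary gland of FVB/n mice, and CAF are fibroblasts from the mammary carcinomas of MMTV-PyMT mice, in which a viral oncogene drives tumours of the mammary epithelium. All cells received 100 nM siRNA, either a control pool or a pool against Hsp90aa1 or Hsp90ab1, the genes of the inducible and the constitutive cytosolic HSP90 chaperone. NF with control siRNA were measured with vehicle and with 5 ng/mL TGFb1, a cytokine that turns fibroblasts into myofibroblasts, and NF with either knockdown were measured with TGFb1. CAF with control siRNA or either knockdown received vehicle, and RNA was taken 48 h after transfection. The p-values measure the spread between these libraries only, since the labels do not say that the replicates are separate cultures or animals.

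Each siRNA pool lowered its own target, to between 9.96% and 13.3% of the matched control. Hsp90aa1 (ENSMUSG00000021270, GRCm38 chromosome 12, 110690605 to 110702728, minus strand) stood at 705 ± 131 normalised CPM (counts scaled to library size; SD, n = 3) in NF with vehicle and 607 ± 63.9 with TGFb1. With siHsp90aa1 it was 75.4 ± 41.0 CPM in NF, 12.4% of the matched control, and in CAF it went from 883 ± 140 to 88.7 ± 32.1 CPM, 10.0% of the control. Hsp90ab1 (ENSMUSG00000023944, chromosome 17, 45567775 to 45573271, minus strand) stood at 3895 ± 561 CPM in NF with vehicle and 3450 ± 331 with TGFb1, and siHsp90ab1 left 460 ± 150 CPM, 13.3% of the control. In CAF, Hsp90ab1 went from 2434 ± 89.8 to 242 ± 74.2 CPM with siHsp90ab1, 9.96% of the control. The log2 fold changes of the targets were -3.01 ± 0.32 (SE) and -3.31 ± 0.33 for Hsp90aa1 in NF and CAF (adjusted p = 7.8e-06 and 4.2e-06) and -2.91 ± 0.21 and -3.33 ± 0.22 for Hsp90ab1 (adjusted p = 1.0e-06 and 1.5e-07).

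With siHsp90aa1, Hsp90ab1 was 3079 ± 134 CPM in NF (adjusted p = 0.580) and 2061 ± 45.2 CPM in CAF (adjusted p = 0.413). With siHsp90ab1, Hsp90aa1 was 292 ± 37.3 CPM in NF, 48.1% of the control (log2 -1.05 ± 0.30, adjusted p = 0.0722), and 420 ± 84.4 CPM in CAF, 47.6% of the control (log2 -1.07 ± 0.30, adjusted p = 0.123). These values of Hsp90aa1 did not pass in edgeR and did pass in DESeq2 (adjusted p = 0.0115 in NF and 0.0181 in CAF), with adjusted p from 0.00187 to 0.292 in NF and from 0.0181 to 0.384 in CAF over all alternatives. Of the other HSP90 genes, Trap1, the mitochondrial member, rose with siHsp90aa1 in NF (0.56 ± 0.10, adjusted p = 0.000385). TGFb1 had lowered it (-0.49 ± 0.10, adjusted p = 0.000867), and it stood at 104 CPM with vehicle, 73.6 with TGFb1 and 109 with siHsp90aa1. In CAF Trap1 did not pass with siHsp90aa1 (0.10 ± 0.10, adjusted p = 0.508). Hsp90b1, the member of the endoplasmic reticulum, stood at 922 ± 127 CPM in NF with TGFb1 and 790 ± 25.2 CPM with siHsp90aa1.

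**Figure D1:**
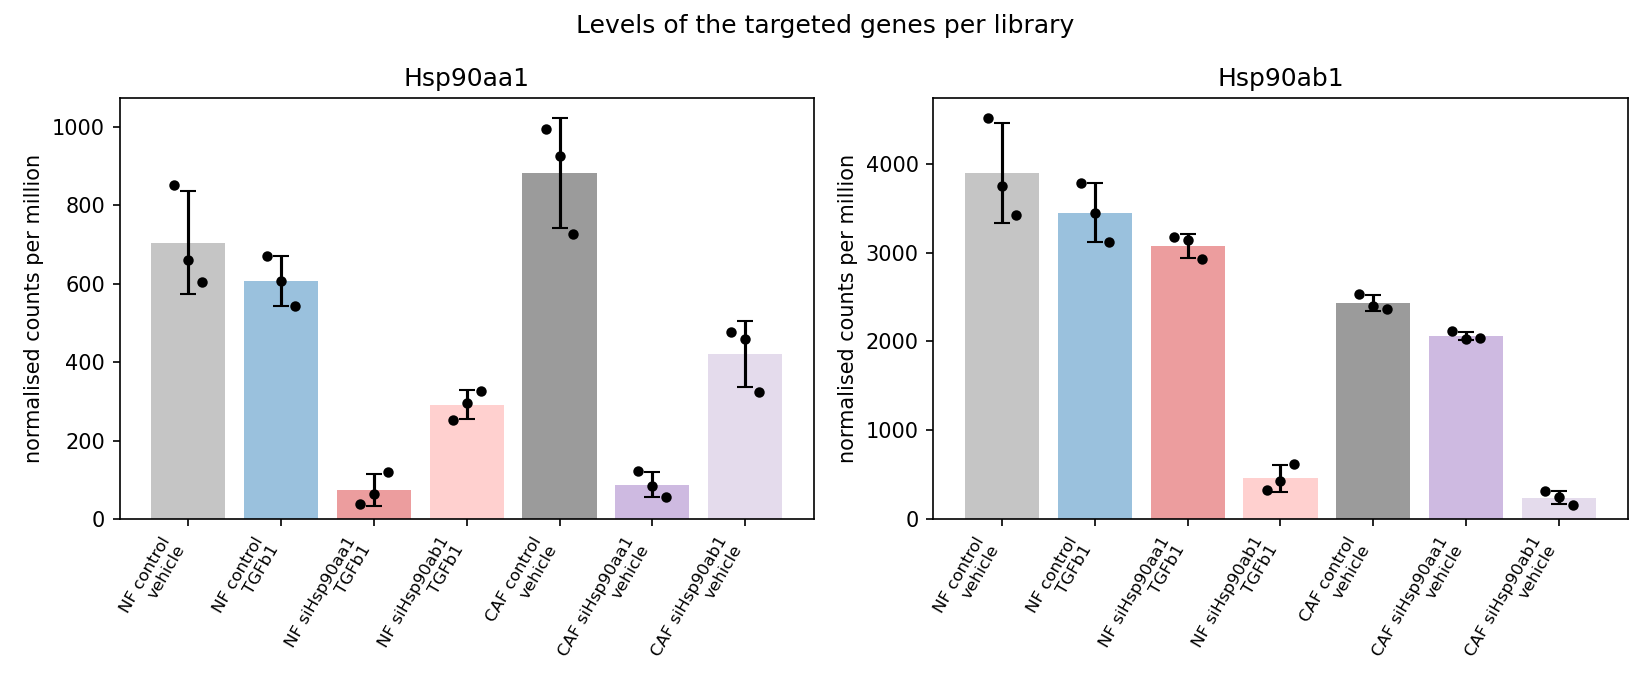
Normalised CPM (linear axes from 0) of Hsp90aa1 and Hsp90ab1 in each of the 7 groups. Bars are means of 3 libraries, whiskers the SD and points single libraries. The mean of Hsp90aa1 is 75.4 in NF and 88.7 in CAF with its siRNA, and that of Hsp90ab1 is 460 and 242 with its siRNA.

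Cell origin was the main axis of the data. All libraries are labelled NF1 or CAF1, so origin cannot be told apart from the single numbered line of each kind. The first principal component held 73.9% of the variance and parted CAF, at group means from 103 to 116, from NF, at -78.6 to -84.9. The second held 7.95% and followed TGFb1 in NF, from 55.0 ± 4.17 (SD, n = 3) with vehicle to -29.5 ± 3.66 with TGFb1. On this axis NF with TGFb1 and siHsp90aa1 lay between them at 20.1 ± 7.85, whereas NF with TGFb1 and siHsp90ab1 lay beyond TGFb1 alone at -45.6 ± 3.71. On the third component, with 4.63% of the variance, NF with TGFb1 and siHsp90aa1 lay outside both at -28.3 ± 5.62. Vehicle lay there at 24.0 ± 10.7 and TGFb1 at 2.40 ± 11.2. CAF with siHsp90aa1 lay low on it too, at -31.3 ± 15.6 against 16.3 ± 22.1 in CAF controls. Mitochondrial genes took 3.02 ± 1.13% of counts in NF with vehicle (4.30% in replicate 1), 2.31 ± 0.449% with TGFb1, 2.34 ± 0.170% with siHsp90aa1 and 2.07 ± 0.110% with siHsp90ab1. In CAF these shares were 1.77 ± 0.0895% with control siRNA, 1.84 ± 0.160% with siHsp90aa1 and 1.69 ± 0.0314% with siHsp90ab1. Markers of other cell types stayed low in most cases. Krt19, the highest epithelial marker, stood at 13.5 CPM in CAF, the endothelial gene Kdr reached 9.28 CPM in CAF with siHsp90ab1 and the myeloid gene Csf1r 6.41 CPM in NF with siHsp90ab1. Pdgfrb, a pericyte marker that fibroblasts also express, ranged from 210 to 405 CPM. None of the 40 tests of the 5 marker lists passed in camera (lowest adjusted p = 0.702), but the lists had only 2 to 6 tested members. In edgeR 3 of 6 endothelial, 2 of 4 pericyte and 1 of 2 glial markers were higher in CAF than in NF. Of 4 epithelial markers 1 was higher and 2 were lower, and of 3 immune markers 0 passed (1 lower with the replicate block).

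**Figure D2:**
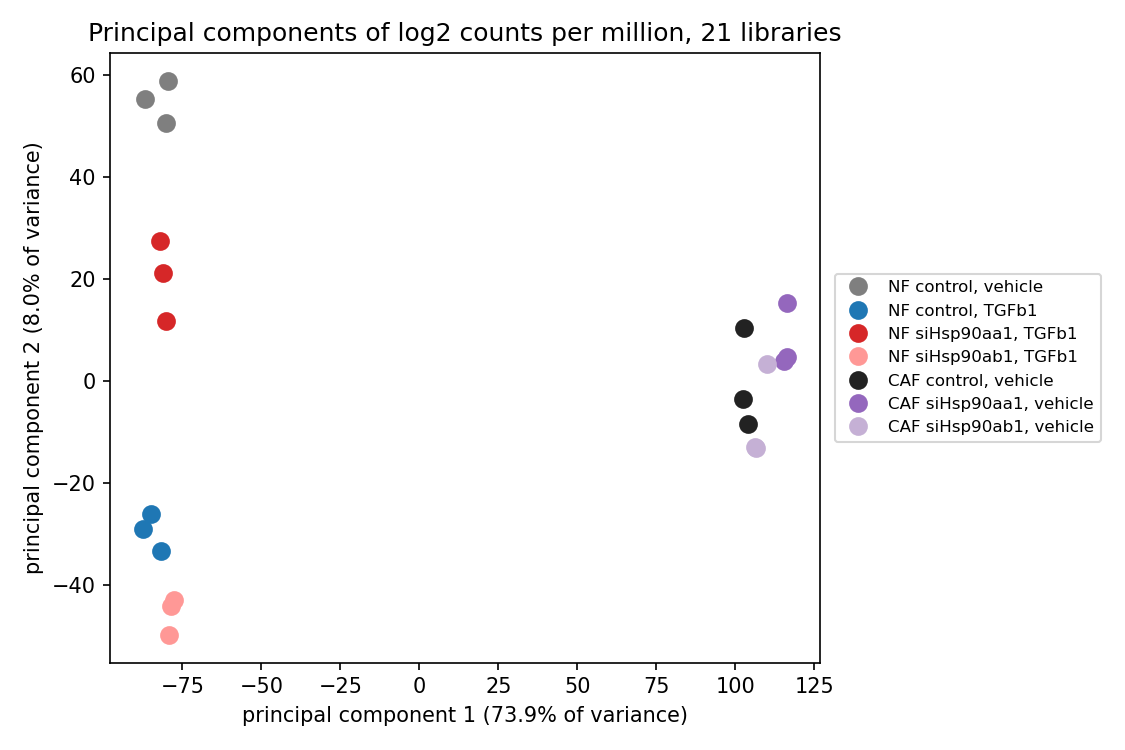
First and second principal components (arbitrary units) of log2 CPM, 1 point per library, coloured by group. CAF lie to the right of NF, and NF with TGFb1 and siHsp90aa1 have a mean of 20.1 on the second axis, between vehicle at 55.0 and TGFb1 at -29.5.

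The comparison of CAF with NF, both with control siRNA and vehicle, asks how these fibroblast lines of tumour and normal gland differ. CAF carried a strong myofibroblast and matrix programme. Of 27 matrix genes 24 were higher and 1 lower than in NF (25 and 1 adjusted over the list alone), with Col11a1 at 8.18 ± 0.22 and Col12a1 at 5.97 ± 0.16 (log2, SE, n = 3 per group). Of 23 contractile genes 19 were higher and 2 lower (20 and 2 adjusted over the list alone), with the smooth muscle genes Tagln at 5.84 ± 0.22, Cnn1 at 5.56 ± 0.20 and Acta2 at 4.35 ± 0.23. The interferon-stimulated genes went the other way, and all 22 were lower in CAF, including Irf9 (-2.56 ± 0.12), a transcription factor gene of the interferon response. The largest single differences included Pgr, the progesterone receptor, at 171 ± 36.0 CPM (SD) in CAF and 0.129 ± 0.117 CPM in NF (10.4 ± 0.42), the homeobox gene Alx4 and the secreted matrix protein gene Cthrc1. Highest on the NF side were Trim30a, Hunk, Wasf3, Sh3rf2, Gbp5, Cxcl11 and Nos2, the inducible nitric oxide synthase.

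Enzymes that process and crosslink collagen were higher in CAF, 17 of 19, with Loxl2 at 8.92 ± 0.30 and Lox at 2.60 ± 0.15. So were 13 of 18 matrix proteases and inhibitors (14 adjusted over the list alone), with 3 lower and the gelatinase gene Mmp2 at 4.07 ± 0.23. TGFb signalling targets were higher in 15 of 22 cases and lower in 3, with Nox4 at 2.89 ± 0.20. Cytokines and chemokines were lower, 12 of 20 with 4 higher, led by the neutrophil chemokine gene Cxcl1 (-4.23 ± 0.23) and the complement gene C3 (-5.83 ± 0.33). Lower too were 13 of 26 cell cycle genes with 1 higher, such as the replicative helicase gene Mcm3 (-1.13 ± 0.17). Hypoxia and glycolysis genes were lower in 14 of 19 cases and higher in 1, with Pfkp at -1.06 ± 0.09. With the replicate number as a block 2 cell cycle genes and 2 hypoxia and glycolysis genes were higher. In camera the adjusted p was 3.6e-15 for interferon-stimulated genes, 5.2e-10 for matrix, 3.9e-07 for collagen processing, 5.0e-07 for contractile genes and 0.00332 for hypoxia and glycolysis. It was 0.00757 for the cell cycle, 0.00936 for cytokines, 0.0140 for TGFb targets and 0.0253 for proteases. With an estimated correlation no list passed, and the adjusted p was 0.181 for matrix, 0.425 for interferon-stimulated genes, collagen processing, contractile genes and hypoxia, 0.544 for cytokines, 0.568 for TGFb targets, 0.636 for proteases and 0.751 for the cell cycle. Targets of SRF, a transcription factor of the cytoskeleton, missed the threshold at adjusted p = 0.0653 (9 of 19 higher, 3 lower) and passed with the replicate number as a block at adjusted p = 0.0373.

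In all, 9378 of 15230 genes differed between CAF and NF in edgeR, 4808 higher and 4570 lower, and 2282 and 1614 of them by more than 2-fold. Without NF vehicle replicate 1, the library with the highest mitochondrial share, the count was 8991. Rxfp1, Fbxl7, Aldh1a2, Fam83g and Brinp1 had no counts in NF and were at least 498-fold, 356-fold, 352-fold, 315-fold and 290-fold higher in CAF, measured against a floor of 3 counts over the group. Mab21l1 and Dgkk, with few counts in NF, had CAF to NF ratios of 2509 (95% exact interval 450 to 99159) and 1850 (332 to 73107). Trim30d and Ppp1r14c, with few counts in CAF, had NF to CAF ratios of 1304 (361 to 10775) and 1133 (203 to 44801). Hsp90ab1 itself was lower in CAF (-0.68 ± 0.20, adjusted p = 0.00645), as was Trap1 (-0.65 ± 0.10), and Hsp90aa1 did not pass (0.32 ± 0.30, adjusted p = 0.361).

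TGFb1 in NF asks which part of the CAF programme the cytokine induces in normal fibroblasts. It raised 20 of 22 TGFb signalling targets, with the growth factor gene Pdgfb rising from 0.332 ± 0.0749 to 39.9 ± 6.97 CPM (6.89 ± 0.38) and the transcription factor gene Snai1 by 1.54 ± 0.09. Contractile genes rose in 18 of 23 cases and fell in 1 (20 and 2 adjusted over the list alone), with Tagln at 3.16 ± 0.20 and Acta2 at 2.93 ± 0.21. Matrix genes rose in 18 of 27 cases and fell in 2 (19 and 2 adjusted over the list alone), with Col1a1, a chain of type I collagen, at 1.95 ± 0.16. Genes of resting and adipogenic fibroblasts fell, 10 of 20 with 2 rising (12 and 2 adjusted over the list alone), among them the surface marker genes Ly6a (-2.98 ± 0.20) and Pdgfra (-1.54 ± 0.14). The largest rises were Ctsw, Cilp, Pdgfb, Wnt11, Acsbg1, Aldh1a3, Fgf2, Olfm2, Abcb1a and Prg4, from 4.86 to 8.70. The largest falls were Galnt15, Ggt5, Ranbp3l, Dio3, Ptpn5, Nov, Ly6c1, Saa3, Itgb7 and Sfrp2, from -3.42 to -5.75.

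The amino acid and stress genes of the integrated stress response rose as well, 14 of 20 (15 adjusted over the list alone), with their transcription factor gene Atf4 at 0.78 ± 0.08. Of 18 endoplasmic reticulum chaperone genes 7 rose (11 adjusted over the list alone), with Xbp1 at 0.95 ± 0.14. Of 19 collagen processing genes 13 rose, led by Lox (2.07 ± 0.14), and of 19 SRF targets 12 rose (13 higher and 1 lower adjusted over the list alone), led by Pdlim7 (1.79 ± 0.09). Of 22 growth factor genes 11 rose and 4 fell (11 and 6 adjusted over the list alone), with Pdgfa at 2.46 ± 0.21 and Fgf10 at -1.88 ± 0.16. Proteases and inhibitors rose in 9 of 18 cases and fell in 3, with a median of 0.48 and a mean of 0.01 that includes 1 member with no counts after TGFb1. Of this list Adamts5 fell (-2.48 ± 0.29) and Adam12 rose (2.52 ± 0.18). Cytokines fell in 11 of 20 cases and rose in 3 (12 and 4 adjusted over the list alone), with Cxcl1 at -2.22 ± 0.21. Cell cycle genes fell in 8 of 26 cases (12 adjusted over the list alone), with Mcm7 at -0.41 ± 0.10, and interferon-stimulated genes in 5 of 22 (4 adjusted over the list alone), with Ifi44 at -1.01 ± 0.27. In the fit with the replicate block 17 cell cycle and 8 interferon-stimulated genes fell and 11 chaperone genes rose.

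For these lists under TGFb1 the adjusted p in camera was 3.6e-15 for TGFb targets, 9.8e-11 for contractile genes, 1.3e-07 for matrix, 1.7e-07 for the integrated stress response, 2.2e-06 for collagen processing and 2.7e-06 for SRF targets. It was 0.000769 for endoplasmic reticulum chaperones, 0.000901 for the cell cycle, 0.00117 for interferon-stimulated genes, 0.00381 for resting fibroblast genes, 0.00599 for cytokines, 0.0118 for growth factors and 0.0290 for proteases. With an estimated correlation the adjusted p was 0.147 for TGFb targets, 0.285 for matrix, 0.386 for contractile genes, 0.425 for the stress response and collagen processing, 0.449 for SRF targets and chaperones, 0.478 for resting fibroblast genes, 0.544 for cytokines and growth factors, 0.649 for proteases, 0.666 for interferon-stimulated genes and 0.700 for the cell cycle. In edgeR 4410 genes passed, 2223 higher and 2187 lower, with 724 and 669 beyond 2-fold, and 4291 passed without NF vehicle replicate 1. Of the genes that passed here, 2438 differed in the same direction between CAF and NF and 721 in the opposite direction, against 1358 for independent calls. The covariance of log2 fold changes was 0.430 against 0.0113 in 25 simulations of unchanged groups with the same controls.

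**Figure D3:**
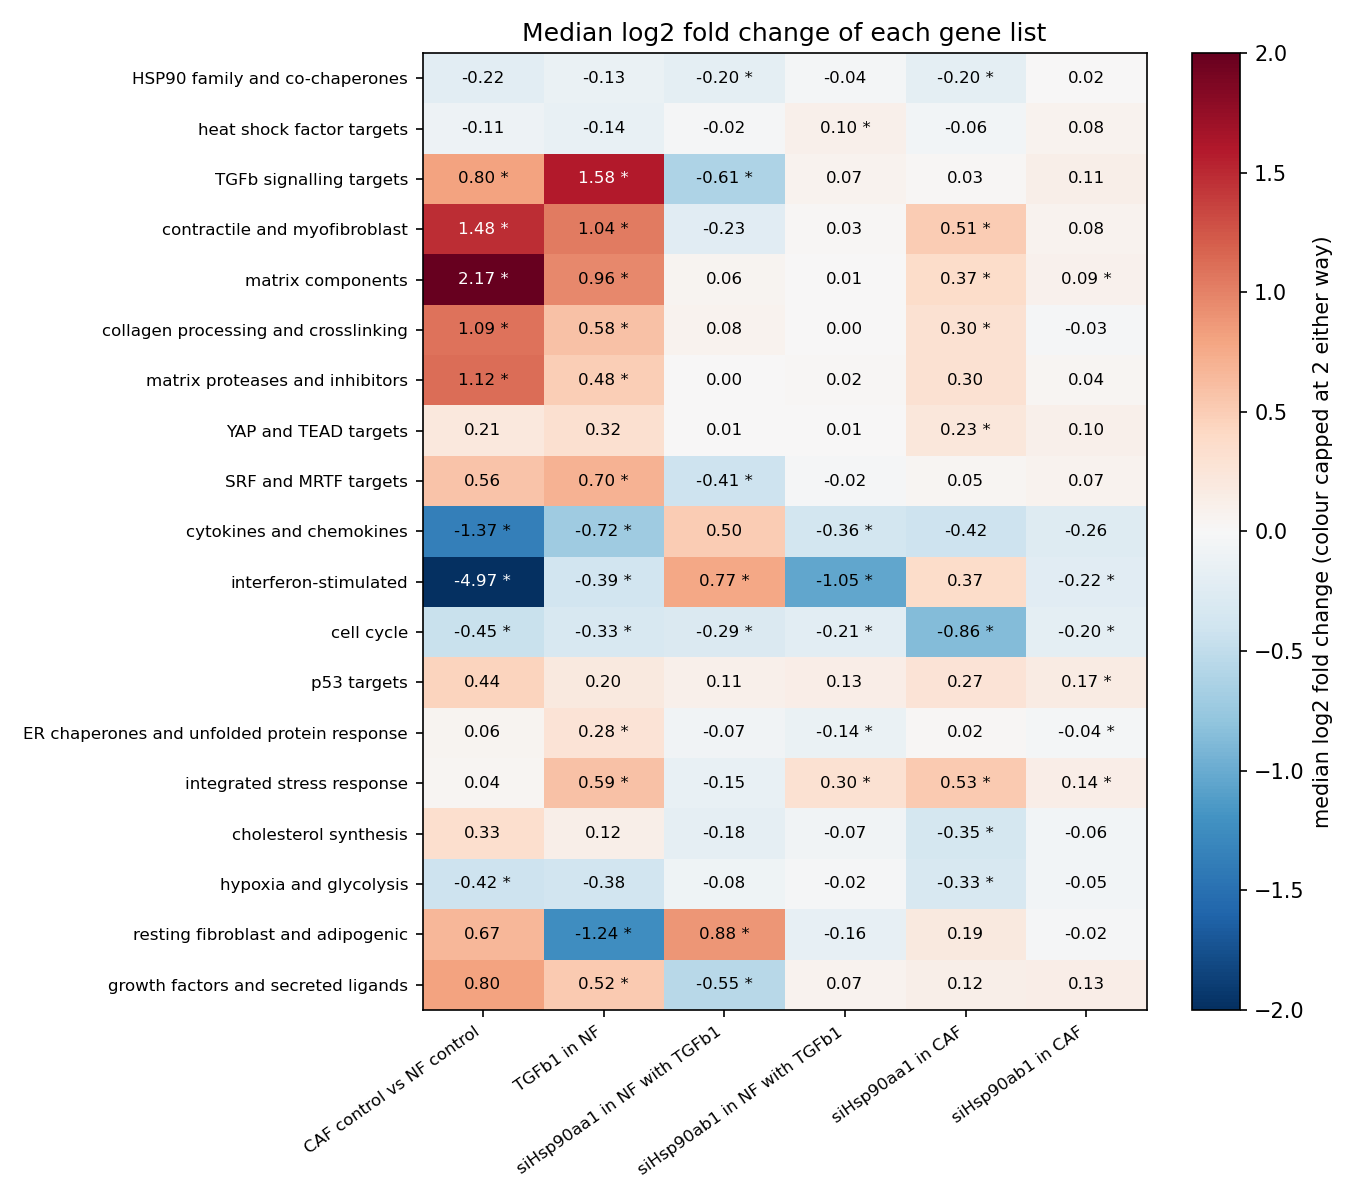
Median log2 fold change of 19 gene lists in 6 comparisons, with colour capped at 2 either way. An asterisk marks a list that passed in camera with a preset correlation (152 tests adjusted together), and none passed with an estimated correlation. Interferon-stimulated genes have a median of 0.77 with siHsp90aa1 and -1.05 with siHsp90ab1 in NF.

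Knockdown of Hsp90aa1 in NF with TGFb1 asks how loss of the inducible isoform changes cells that received the cytokine. No NF knockdown was measured with vehicle, so effects of the siRNA that do not depend on TGFb1 are not separated. Genes that TGFb1 had lowered came back, with Ly6a rising from 27.1 ± 3.84 to 217 ± 70.2 CPM (3.00 ± 0.20), Ly6c1 by 3.15 ± 0.27 and Pdgfra by 1.22 ± 0.14. Of 20 resting and adipogenic fibroblast genes 7 rose and 2 fell. TGFb signalling targets fell, 11 of 22 with 1 rising (12 and 1 adjusted over the list alone), among them Tgfbr1, which encodes the type I receptor (-1.32 ± 0.13), Tgfb1 itself (-1.18 ± 0.17) and Pdgfb (-1.66 ± 0.27). The largest rises were Ggt5, Wisp2, Ly6c1, Ptpn5, Ly6a, Plin4, Mrgprf, Prl2c2, Tmem86a and Abi3bp, from 2.56 to 4.39. After Hsp90aa1 the largest falls were Lad1, Cmklr1, Acsbg1, Fgf2, Sema7a, Tnnt2, Tmem151b, Alcam and Inhba, from -2.06 to -2.66. Of these Inhba lost its call without NF siHsp90aa1 replicate 1 (adjusted p = 0.0515) and Sema7a without NF siHsp90aa1 replicate 1 or 2 or NF TGFb1 replicate 1 (adjusted p = 0.0606, 0.0766 and 0.0697).

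Interferon-stimulated genes rose with siHsp90aa1 in NF, 16 of 22 (17 adjusted over the list alone), with Cxcl10 at 1.48 ± 0.30 and Irf7, a transcription factor of the interferon response, at 1.38 ± 0.27. Growth factor genes fell in 8 of 22 cases and rose in 3 (9 and 3 adjusted over the list alone), with Pdgfa at -1.82 ± 0.20 and Wnt5a at -1.33 ± 0.14, and SRF targets fell in 6 of 19 and rose in 1 (9 and 2 adjusted over the list alone), with Cotl1 at -1.22 ± 0.18. Cell cycle genes fell in 8 of 26 cases, with Mcm3 at -1.24 ± 0.18, and genes of the HSP90 and co-chaperone list, which holds Hsp90aa1 itself, in 5 of 15 with 1 rising. Under the replicate block 18 of 26 cell cycle genes fell, 10 SRF targets fell and 2 rose, and 2 TGFb targets rose. In camera the adjusted p was 7.8e-10 for interferon-stimulated genes, 0.000109 for the cell cycle, 0.000201 for TGFb targets, 0.00235 for resting fibroblast genes, 0.0110 for SRF targets, 0.0375 for HSP90 and co-chaperones and 0.0415 for growth factors. With an estimated correlation the adjusted p was 0.425 for TGFb targets, 0.449 for interferon-stimulated and resting fibroblast genes, 0.600 for HSP90 and co-chaperones and for growth factors, and 0.656 for the cell cycle and SRF targets. Matrix genes (median 0.06, adjusted p = 0.711) and contractile genes (median -0.23, adjusted p = 0.112) did not pass, although Tagln fell (-0.88 ± 0.18) and Thbs2, a matrix gene, rose (1.62 ± 0.27). In edgeR 4309 genes passed, 2247 higher and 2062 lower.

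The knockdown of Hsp90aa1 moved much of the TGFb1 response in NF the other way, and that of Hsp90ab1 did not. Of the 724 genes that TGFb1 raised over 2-fold, 293 (40.5%) fell with siHsp90aa1 and 4 rose, and of the 669 that it lowered, 400 (59.8%) rose and 1 fell. With siHsp90ab1, 1 of the raised genes fell and 18 rose, and 3 of the lowered genes rose and 33 fell. The median change of the raised genes was 1.78 with TGFb1, then -0.67 with siHsp90aa1 and 0.09 with siHsp90ab1, and that of the lowered genes was -1.66, then 1.12 and -0.05. Both knockdowns share their control libraries with the TGFb1 comparison, so the knockdowns were also set against each other. In siHsp90aa1 against siHsp90ab1, which uses none of those libraries, the raised genes had a median of -0.77 (377 lower, 6 higher, camera adjusted p = 1.3e-25) and the lowered genes 1.16 (401 higher, 4 lower, adjusted p = 4.9e-28), and both passed with an estimated correlation (adjusted p = 0.00489 for each). The replicate block changes the lists to 765 raised genes, of which 461 were lower and 12 higher, and 722 lowered genes, of which 471 were higher and 9 lower. This contrast was added after the data were examined. It also holds the changes with siHsp90ab1, so its size is not that of siHsp90aa1 alone. Over all genes 1796 passed in opposite directions with TGFb1 and siHsp90aa1 and 124 in the same direction, against 624 opposite for independent calls (331 in the same direction with the replicate block). The covariance of their log2 fold changes was -0.414 against -0.0104 simulated for unchanged groups with these controls and independent libraries. With TGFb1 and siHsp90ab1 29 genes passed in opposite directions and 175 in the same direction, against 59.2 opposite for independent calls. With the replicate block these counts were 82 and 440.

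**Figure D4:**
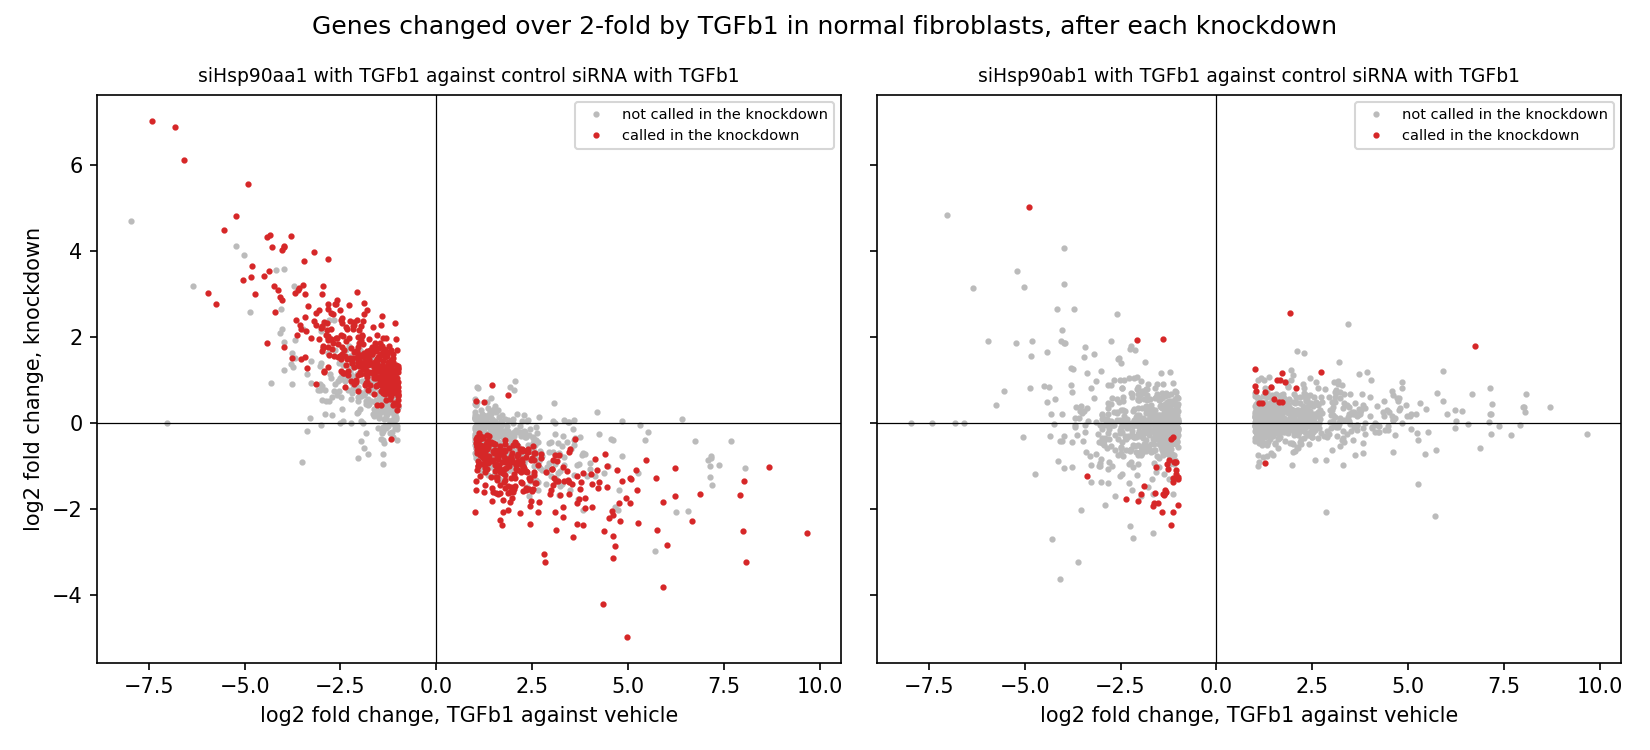
Log2 fold change with TGFb1 (horizontal) against that after each knockdown (vertical) in NF, for 1393 genes that TGFb1 changed over 2-fold. Each point is a gene, and red points passed in the knockdown. With siHsp90aa1 the medians are -0.67 for raised and 1.12 for lowered genes, and with siHsp90ab1 they are 0.09 and -0.05.

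Knockdown of Hsp90ab1 in NF with TGFb1 lowered interferon-stimulated genes, although the list did not pass with an estimated correlation. Of 22 interferon-stimulated genes 14 fell (21 adjusted over the list alone), with Stat2 at -1.07 ± 0.19 and the chemokine gene Cxcl10 going from 263 ± 106 to 70.9 ± 8.10 CPM (-1.89 ± 0.30). The largest falls after Hsp90ab1 included the guanylate-binding protein gene Gbp5 (-2.06 ± 0.26), the antiviral genes Oas3, Iigp1 and Mx1, and Ifit3, Ifit3b, Cmpk2 and Rsad2. Of these only Ifit3 and Rsad2 belong to the fixed list. Ifit3, Ifit3b, Cmpk2 and Rsad2 missed the threshold without either NF TGFb1 replicate 1 or 2 or any single siHsp90ab1 library (adjusted p from 0.0557 for Ifit3 to 0.166 for Rsad2). Smaller rises were seen in Stc2, Lpin3, Acp1, Zbtb18, Adm2, Nek3, Dnajc24 and Lrig3, from 0.87 for Lrig3 to 1.30 for Stc2. Of 20 genes of the integrated stress response 2 rose (6 adjusted over the list alone, 9 with the replicate block). The lists of the TGFb programme did not pass, with medians of 0.07 for TGFb targets, 0.01 for matrix and 0.03 for contractile genes (adjusted p = 0.560, 0.305 and 0.920).

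Of the remaining lists with siHsp90ab1 in NF, the cell cycle had a median of -0.21 with 1 of 26 members lower, endoplasmic reticulum chaperones -0.14 with 1 of 18 lower (3 adjusted over the list alone), cytokines -0.36 with 1 of 20 lower and heat shock factor targets 0.10 with 1 of 18 higher (3 higher and 1 lower adjusted over the list alone), the small heat shock protein gene Hspb1 at 0.69 ± 0.09. In the blocked fit 6 cell cycle, 3 chaperone and 3 cytokine genes fell and 3 heat shock factor targets rose. In camera the adjusted p was 3.7e-32 for interferon-stimulated genes, 3.8e-08 for the integrated stress response, 7.1e-06 for the cell cycle, 0.00599 for chaperones, 0.00908 for cytokines and 0.0281 for heat shock factor targets. When the correlation was estimated, the adjusted p was 0.181 for interferon-stimulated genes, 0.425 for the stress response, 0.544 for chaperones and cytokines, 0.600 for heat shock factor targets and 0.633 for the cell cycle. In edgeR 409 genes passed, 162 higher and 247 lower, and 902 passed with the replicate number as a block. The count rested on single libraries and was 157, 180 and 270 without NF siHsp90ab1 replicate 1, 2 and 3, and 162 and 184 without NF TGFb1 replicate 1 and 2.

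Knockdown of Hsp90aa1 in CAF asks what the isoform does in fibroblasts that already carry the tumour programme. The cell cycle fell, with 25 of 26 genes lower (26 adjusted over the list alone), including the sliding clamp gene Pcna (-1.28 ± 0.13) and the helicase gene Mcm3 (117 ± 23.2 to 35.6 ± 10.1 CPM, -1.72 ± 0.18). Contractile and matrix genes rose rather than fell, 11 of 23 (16 adjusted over the list alone) and 12 of 27 (13 adjusted over the list alone), with Tpm1 at 0.58 ± 0.11, Col8a1 at 0.99 ± 0.18 and the crosslinking enzyme gene Lox at 0.93 ± 0.14. TGFb signalling targets had a median of 0.03 (adjusted p = 0.709), although Tgfbr1 fell as in NF (-1.02 ± 0.12). After Hsp90aa1 the largest falls were Parvb, Ak4, Met, Bmper, Dna2, Etv1, Mcm3, Bcl6b and Slc5a3, from -1.70 to -2.16, and the rises that held without any 1 library were Myom1, Parm1, Tcp11l2, Lims2, Pappa, Slc24a3 and C1qtnf3, from 1.70 to 1.98.

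Genes of the integrated stress response rose in CAF with siHsp90aa1, 14 of 20, with the amino acid transporter subunit gene Slc3a2 at 0.72 ± 0.09. Glycolysis and hypoxia genes fell in 9 of 19 cases (10 lower and 1 higher adjusted over the list alone), with Eno1 at -0.49 ± 0.07 and Ldha at -0.60 ± 0.10, and cholesterol synthesis genes in 7 of 20 (8 adjusted over the list alone). Collagen processing genes rose in 7 of 19 cases and YAP targets in 8 of 22 with 1 lower (2 lower adjusted over the list alone), and the HSP90 and co-chaperone list fell in 6 of 15, Hsp90aa1 itself among them, with Fkbp4 at -0.67 ± 0.09. With the replicate block 2 hypoxia and glycolysis genes rose, and 2 YAP targets and 1 contractile gene fell. In camera the adjusted p was 1.4e-20 for the cell cycle, 3.3e-05 for contractile genes, 3.6e-05 for the stress response, 0.000173 for matrix and collagen processing, 0.000478 for cholesterol synthesis, 0.00139 for HSP90 and co-chaperones, 0.00381 for hypoxia and glycolysis and 0.0253 for YAP targets. Under an estimated correlation the adjusted p was 0.425 for the cell cycle, matrix and hypoxia, 0.449 for contractile genes, collagen processing, HSP90 and co-chaperones and YAP targets, 0.513 for the stress response and 0.600 for cholesterol synthesis. The 10 most abundant genes of each library took 10.6 ± 0.451% of counts with siHsp90aa1 and 8.55 ± 0.540% in the CAF control. In edgeR 3867 genes passed, 1898 higher and 1969 lower, with 2460 without CAF control replicate 2 and 2524 without CAF siHsp90aa1 replicate 3.

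Knockdown of Hsp90ab1 in CAF changed few genes. After Hsp90ab1 the falls that held without any 1 library were Ppp1r14b, P2rx7, Klhl23, the nuclear receptor gene Ppard, the dystroglycan gene Dag1, Pdia6 and Rnf7, from -0.71 to -1.11, and the rises were Zbtb18, a transcriptional repressor gene, Acp1, Ammecr1 (1.03 ± 0.10), Dnajc24, Dhrs9 and Dcun1d3 (0.78 ± 0.10). Of these, Ppp1r14b, P2rx7, Klhl23, Dag1, Pdia6, Rnf7, Acp1, Ammecr1, Dnajc24, Dhrs9 and Dcun1d3 missed the threshold when the fit held only the 6 compared libraries (adjusted p from 0.0561 for Ammecr1 to 0.164 for Pdia6), and Zbtb18 and Ppard kept it. Zbtb18, Acp1 and Dnajc24 also rose in NF with the same siRNA. Ppp1r14b, Ppard, Dag1 and Pdia6 fell in NF as well and hold in their 3' UTRs the 7-base word ACTGACG. Of all words tested, genes with this word, 322 in number, were lowest with this siRNA in NF and also in CAF. The word was picked on the NF values, so its presence in genes that fell there is no separate evidence. It lies in 0 of 8 annotated Hsp90ab1 transcripts. The lists that passed in camera, none of them with an estimated correlation, had small medians, -0.20 for the cell cycle, -0.22 for interferon-stimulated genes, 0.14 for the integrated stress response, 0.17 for p53 targets, 0.09 for matrix and -0.04 for endoplasmic reticulum chaperones. At most 1 member of each passed in edgeR, and of the cell cycle genes Mcm4 came closest (adjusted p = 0.0809, 0.00364 with the replicate block, with which 3 cell cycle and 2 chaperone genes fell).

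In camera the adjusted p for siHsp90ab1 in CAF was 2.5e-06 for the cell cycle, 0.00159 for interferon-stimulated genes, 0.00490 for the stress response, 0.0220 for matrix, 0.0309 for p53 targets and 0.0449 for chaperones. An estimated correlation gave an adjusted p of 0.449 for p53 targets, 0.568 for matrix, 0.600 for the cell cycle, 0.649 for the stress response, 0.656 for chaperones and 0.668 for interferon-stimulated genes. With the replicate block heat shock factor targets (adjusted p = 0.0304), TGFb targets (0.0374) and YAP targets (0.0244) passed as well, and without CAF control replicate 2 only 2 lists did. In edgeR 137 genes passed, 71 higher and 66 lower, and 360 with the replicate number as a block. Far fewer passed in a fit of the compared groups alone, and more in DESeq2. The count was 80, 55 and 55 without CAF siHsp90ab1 replicate 1, 2 and 3, and 44 and 59 without CAF control replicate 2 and 3.

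Set against each other, the knockdowns gave opposite interferon states in NF. Of 22 interferon-stimulated genes 21 were higher with siHsp90aa1 than with siHsp90ab1 (22 adjusted over the list alone, median 1.77, camera adjusted p = 7.9e-20, adjusted p = 0.417 with an estimated correlation). The largest differences were Ggt5, Trim30d, Gbp5, Tnfsf10 and Mx1 on the siHsp90aa1 side and Acsbg1, Alcam, Sema7a, Npr3 and the anchoring collagen gene Col7a1 (-2.40 ± 0.21) on the siHsp90ab1 side. TGFb targets were lower with siHsp90aa1 in 14 of 22 cases (median -0.79, adjusted p = 0.000201), the stress response in 12 of 20 (14 adjusted over the list alone, median -0.44, adjusted p = 3.3e-05), growth factors in 10 of 22 with 3 higher (-0.56, adjusted p = 0.0260) and SRF targets in 9 of 19 (9 lower and 1 higher adjusted over the list alone, median -0.39, adjusted p = 0.0191). Cytokines were higher in 10 of 20 with 1 lower (0.83, adjusted p = 0.00897) and resting fibroblast genes in 9 of 20 with 1 lower (0.94, adjusted p = 0.0120). With the replicate block 2 cytokine and 3 resting fibroblast genes were lower and 1 SRF target higher. When the correlation was estimated, the adjusted p was 0.425 for TGFb targets, 0.513 for the stress response, 0.544 for cytokines and resting fibroblast genes, 0.568 for growth factors and 0.666 for SRF targets. In edgeR 5201 genes differed, 2701 higher and 2500 lower with siHsp90aa1.

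By p in camera the knockdowns differed most in CAF in the cell cycle, with 25 of 26 genes lower with siHsp90aa1 (26 adjusted over the list alone, median -0.67, adjusted p = 2.7e-15). Interferon-stimulated genes were higher with it in 8 of 22 cases (0.71, adjusted p = 0.00381), as were contractile genes in 10 of 23 (0.40, adjusted p = 0.00110), matrix in 8 of 27 (0.29, adjusted p = 0.00644), collagen processing in 6 of 19 (0.28, adjusted p = 0.000221) and the stress response in 9 of 20 (0.37, adjusted p = 0.00381). In that order 12, 13, 9, 8 and 11 members were higher adjusted over the list alone, with 1 contractile gene lower. Cholesterol synthesis was lower in 4 of 20 (-0.32, adjusted p = 0.00591), hypoxia and glycolysis in 9 of 19 with 2 higher (-0.22, adjusted p = 0.0117) and the HSP90 and co-chaperone list, which holds both targets, in 6 of 15 with 1 higher (7 and 1 adjusted over the list alone, median -0.17, adjusted p = 0.0308). Under the replicate block 14 matrix and 10 collagen processing genes were higher, and 7 cholesterol synthesis genes and 1 contractile gene lower. Under an estimated correlation the adjusted p was 0.425 for the cell cycle and hypoxia, 0.449 for collagen processing, 0.513 for matrix, 0.544 for contractile genes, 0.595 for HSP90 and co-chaperones, 0.636 for the stress response, 0.668 for cholesterol synthesis and 0.700 for interferon-stimulated genes. The largest differences beside the targets were Tcp11l2, Myom1 and Podn, higher with siHsp90aa1, and Acsbg1, Ccbe1, Il18rap, Parvb and Dtx4, lower, and Fbln7 (1.87 ± 0.58, adjusted p = 0.0229) missed the threshold without CAF siHsp90aa1 replicate 3 (adjusted p = 0.219) or siHsp90ab1 replicate 1 or 2 (0.0999 and 0.107). In edgeR 4006 genes differed, 1988 higher and 2018 lower, with 2478 and 2492 without CAF siHsp90ab1 replicate 2 and 1 and 2506 without CAF siHsp90aa1 replicate 3.

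Each siRNA moved many of the same genes in both cell lines. With siHsp90aa1 1855 genes passed in the same direction in NF and CAF and 96 in opposite directions, against 546 for independent calls, and with siHsp90ab1 83 passed in the same direction against 1.81. With the replicate number as a block 211 genes passed in opposite directions with siHsp90aa1, and 209 were shared by the siHsp90ab1 comparisons. Without a single library this count of 83 fell to 34, 46, 41, 43 and 55 (CAF control replicate 2 and 3, CAF siHsp90ab1 replicate 2, 3 and 1) and to 49, 46, 48 and 40 (NF TGFb1 replicate 1 and 2, NF siHsp90ab1 replicate 1 and 2).

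Between the siRNAs the overlap was smaller. In NF 69 genes passed in the same direction with siHsp90aa1 and siHsp90ab1 and 151 in opposite directions, against 57.2 in the same direction for independent calls, and in CAF 66 passed in the same direction and 5 in opposite directions, against 17.2. With the replicate block the same-direction counts were 197 in NF and 179 in CAF, and the opposite ones 307 and 40. In NF the count was 21 and 28 without NF TGFb1 replicate 1 and 2, and 31, 28 and 37 without NF siHsp90ab1 replicate 1, 2 and 3. In CAF it was 23 and 39 without CAF control replicate 2 and 3, and 43, 32 and 28 without CAF siHsp90ab1 replicate 1, 2 and 3. Both pairs share a control group of 3 libraries that cannot be split, and their covariances of log2 fold changes, 0.0946 in NF and 0.0957 in CAF, compare with 0.0104 and 0.0107 simulated for unchanged groups. The simulations draw libraries independently and leave out the pairing by replicate number.

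The genes of the TGFb1 response in NF were also followed in CAF, to which no TGFb1 was added. The raised genes had a median of 0.03 with siHsp90aa1 (camera adjusted p = 0.360) and 0.10 with siHsp90ab1 (adjusted p = 0.00410, adjusted p = 0.375 with an estimated correlation), and the lowered genes 0.07 and -0.00 (adjusted p = 0.817 and 0.828). When genes below 2-fold were included, the raised genes passed with siHsp90aa1 (median 0.07, adjusted p = 0.0143). The lowered genes then passed with siHsp90ab1 (median -0.05, adjusted p = 0.00655). Genes that were over 2-fold lower in CAF than in NF fell in NF with siHsp90ab1, by a median of -0.15 with 140 lower and 3 higher of 1614 (adjusted p = 2.9e-08, adjusted p = 0.0103 with an estimated correlation), and with the replicate block 231 were lower and 16 higher of 1648. With siHsp90aa1 they had a median of 0.25 with 425 higher and 144 lower (adjusted p = 0.000115, adjusted p = 0.0654 with an estimated correlation), and -2.7e-05 when genes below 2-fold were included (adjusted p = 0.923). The 22 interferon-stimulated genes, all lower in CAF with a median of -4.97, overlap with these CAF-low genes. They too fell with siHsp90ab1 and rose with siHsp90aa1 in NF, and the CAF-low genes were not tested without them. Genes over 2-fold higher in CAF had a median of 0.01 with siHsp90aa1 in NF (adjusted p = 0.918) and 0.05 with siHsp90ab1 (adjusted p = 0.0315, adjusted p = 0.310 with an estimated correlation). Between the knockdowns in CAF, a contrast added after the data were examined, the CAF-high genes had a median of 0.13 (adjusted p = 0.0168, adjusted p = 0.269 with an estimated correlation) and the CAF-low genes -0.06 (adjusted p = 0.0824). The CAF-low genes passed there when genes below 2-fold were included (median -0.05, adjusted p = 0.00110).

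The effect of siHsp90aa1 differed between CAF and NF in 832 genes, 372 with a higher and 460 with a lower value in CAF, and that of siHsp90ab1 in 1, Parp11 (0.84 ± 0.11, adjusted p = 0.0101). This test of the difference sets CAF with vehicle against NF with TGFb1, so cell origin and TGFb1 are not separated in it. Genes with a higher value in CAF included the protease gene Ctsf (2.51 ± 0.36), Mn1, Cmklr1 and the Notch ligand gene Jag1, and those with a lower value Ggt5 (-3.64 ± 0.52) and Prl2c2. With the replicate number as a block 1871 genes and 3 genes passed, and the share of higher genes with siHsp90aa1 was 44.7% against 31.4% with upper quartile scaling. The count of 832 was 453 and 482 without NF siHsp90aa1 replicate 1 and 2, 490 without CAF control replicate 2 and also without NF TGFb1 replicate 3, and 540 without CAF siHsp90aa1 replicate 2. In edgeR 3016 of 15230 genes with siHsp90aa1 and 438 with siHsp90ab1 had an unadjusted p under 0.05 for the difference. The share with siHsp90ab1 is below the 0.05 that unchanged genes would give, so these 438 genes are no sign of a difference.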

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

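Chosen only after the results were seen were the tests of shared controls, of TGFb1 action and of a general drift for the TGFb1 genes, of a response to siRNA as such, of misassigned Hsp90 reads, and the list tests of the difference between CAF and NF.

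The effect of siHsp90aa1 differed between CAF and NF, by the interaction test in edgeR, in 832 genes, and that of siHsp90ab1 in 1, Parp11 (0.84). Since NF had TGFb1 and CAF had vehicle, the difference can come from either. The count of 832 was 453 and 482 without NF siHsp90aa1 replicate 1 and 2, 490 without CAF control replicate 2 or NF TGFb1 replicate 3, and 540 without CAF siHsp90aa1 replicate 2. Parp11 missed the threshold without NF TGFb1 replicate 1, CAF control replicate 1 or 2, CAF siHsp90ab1 replicate 1 or NF siHsp90ab1 replicate 2 or 3 (adjusted p from 0.0540 to 0.0698), and 2 genes passed without NF TGFb1 replicate 2. Other genes that differed with siHsp90aa1 were Ctsf (2.51), Smoc2 (2.47), Mn1 (2.38), Cmklr1 (2.33), Jag1 (2.24), Prl2c3 (-3.80), Ggt5 (-3.64), Gbp10 (-3.49), Prl2c2 (-3.43) and Hhip (-3.38), where Prl2c2 and Prl2c3 are close paralogs whose reads are hard to part. Hhip missed the threshold without CAF control replicate 3 (adjusted p = 0.0511), and Smoc2 without any 1 of these libraries except NF TGFb1 replicate 3 and CAF control replicate 3 (adjusted p from 0.0599 to 0.116).

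By the same difference, with camera at a preset correlation, 13 lists passed with siHsp90aa1. Their medians, CAF minus NF, were 0.75 for TGFb signalling targets, 0.56 for contractile genes, 0.40 for matrix, 0.29 for collagen processing, 0.33 for YAP targets, 0.31 for SRF targets, 0.71 for the integrated stress response, 0.54 for growth factors, -0.86 for cytokines, -0.28 for interferon-stimulated genes, -0.58 for the cell cycle, -0.40 for hypoxia and glycolysis and -0.58 for resting fibroblast genes. With siHsp90ab1 they were 0.65 for interferon-stimulated genes, 0.13 for YAP targets and -0.13 for the stress response. With an estimated correlation the lowest adjusted p was 0.328.

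Other splits of the libraries were counted for each comparison. In the 8 comparisons of 3 against 3 libraries the real split gave the most genes, 1 of 10, which is too few splits for a share under 0.05. Every other split mixed libraries of both groups, so a real difference entered the spread within groups and favoured low counts. Real values and the highest of the other splits were 9378 and 0 for CAF against NF, 4410 and 233 for TGFb1, 4309 and 0 for siHsp90aa1 and 409 and 0 for siHsp90ab1 in NF, 3867 and 2 for siHsp90aa1 and 137 and 62 for siHsp90ab1 in CAF, and 5201 and 0 in NF and 4006 and 0 in CAF between the knockdowns. For the difference between CAF and NF 8 of 100 splits were as large for siHsp90aa1 (832 against a highest other of 3806) and 10 of 100 for siHsp90ab1 (1 against 504), the real split included. The other splits of that size all kept the real knockdown groups in at least 1 cell line, so they hold the knockdown effect itself and point to the structure of the samples. The 80 splits that kept neither gave 0 genes for each siRNA in edgeR. They mixed knockdown and control libraries in each group, so the knockdown effect widened the spread and favoured low counts. Chance is left open, since none of the other splits is free of the effect.

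The first pattern is that siHsp90aa1 moved genes of the TGFb1 response the other way in NF. Noise of the shared controls is argued against by siHsp90aa1 against siHsp90ab1, which uses none of them, with a median of -0.77 for the raised genes. That comparison also holds the change with siHsp90ab1, with which the raised genes had a median of 0.09. Complete failure of TGFb1 to act is argued against by 66.7% of these genes that stayed higher than in NF with vehicle. The same vehicle libraries had chosen the genes, which favours a high share, and no share for unchanged groups was computed. Only 35.3% of the lowered genes stayed lower (median -0.62), so weaker action stays open. A general drift with the fall of the cell cycle is argued against by a cell cycle median of -0.0601 in that same comparison, and by siHsp90ab1 in NF, where the cell cycle had a median of -0.21 and the raised genes one of 0.09. A seed match of the siRNA that lowers Tgfbr1 stays open, since the word picked for siHsp90aa1 lies in 1 of 3 annotated 3' UTRs of Tgfbr1, but 22.2% of genes with a 3' UTR of similar length hold it. No NF knockdown group had vehicle, so an effect of siHsp90aa1 on these genes that does not depend on TGFb1 cannot be told apart. That Hsp90aa1 may be needed for the full TGFb1 response is thus a hypothesis. Its test needs a second siRNA of another sequence and knockdown groups with vehicle.

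The second pattern is that interferon-stimulated genes rose with siHsp90aa1 and fell with siHsp90ab1 in NF. An immune response to siRNA as such could not be tested, since all groups, controls included, received 100 nM siRNA. A response common to all pools cancels in each comparison, so the 14 of 22 genes that fell with siHsp90ab1 do not decide it. Whether the rise belongs to the reversal of the TGFb1 response could not be decided. TGFb1 had lowered 31.2% of the genes that rose (5 of 16). Only 5 of 22 members passed as lowered by TGFb1, and all 5 rose, so a larger share was out of reach. Of the 17 members not called lower with TGFb1, 11 rose, while the list as a set was lower with TGFb1 in camera. An immune response to the Hsp90aa1 siRNA alone could not be excluded. In siHsp90aa1 with TGFb1 against NF with vehicle the list had a median of 0.41, but only 2 of 22 members passed as higher and 0 as lower. In CAF with siHsp90aa1 the list did not pass in camera (median 0.37, 2 of 22 higher, adjusted p = 0.198). A role of each isoform in interferon signalling may remain and was not tested apart from the knockdowns.

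The third pattern is the level of Hsp90aa1 at 48.1% and 47.6% of the control with siHsp90ab1, which missed the threshold in edgeR. Reads of Hsp90ab1 counted as Hsp90aa1 could cover 39.1% of the fall in NF and 27.4% in CAF by the library with the highest share (23.6% and 20.3% by the mean share), which argues against them as the whole cause. A seed match stays open, since the word picked for siHsp90ab1 lies in 0 of 8 annotated Hsp90aa1 transcripts but also in none of Hsp90ab1, so it is not shown to belong to the pool. An siRNA in the pool that matches both genes stays open, since transcripts of both share 20 stretches of 19 bases and the siRNA sequences are not given in the sources used here.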

How the results depend on the processing

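Leaving out libraries for lists and overlaps, and the derived lists between the knockdowns, were tests chosen only after the results were seen.

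The cause of the changes below was not tested, except that stricter thresholds pass fewer genes by construction. At adjusted p under 0.01 the counts were 2785 for TGFb1, 2438 and 158 for siHsp90aa1 and siHsp90ab1 in NF, 2146 and 45 in CAF, 3345 and 2154 between the knockdowns in NF and CAF, and 233 and 0 for the difference between CAF and NF with siHsp90aa1 and siHsp90ab1. With a log2 fold change over 1 they were 3896 for CAF against NF, 1393, 884, 99, 485, 9, 1257, 522, 284 and 0 in that order. The difference with siHsp90ab1 gave 438 of 15230 genes at an unadjusted p under 0.05 in edgeR, a share below the 0.05 for unchanged genes. At an adjusted p under 0.05 it gave 18 in DESeq2 and 0 in voom. DESeq2 gave 709 and 322 for siHsp90ab1 in NF and CAF and 1341 for the difference with siHsp90aa1. With the compared groups alone siHsp90ab1 in CAF gave 5. The replicate block gave 902 and 360 for siHsp90ab1 and 1871 and 3 for the differences.

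Lists that passed in camera were 0 in all 8 comparisons with an estimated correlation, and in fry 15 for CAF against NF, 2 for siHsp90ab1 in NF and 0 in CAF. For derived lists the medians were, with an estimated correlation, 0.10 for raised genes with siHsp90ab1 in CAF (adjusted p = 0.375), 0.0461 for CAF-high genes with siHsp90ab1 in NF (0.310), 0.13 for CAF-high genes between knockdowns in CAF (0.269) and 0.25 for CAF-low genes with siHsp90aa1 in NF (0.0654). With no fold change minimum they were 0.0721 for raised genes with siHsp90aa1 in CAF (0.0143), -0.0463 for lowered genes with siHsp90ab1 in CAF (0.00655), -2.7e-05 for CAF-low genes with siHsp90aa1 in NF (0.923) and -0.0522 for CAF-low genes between knockdowns in CAF (0.00110).

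Overlaps at adjusted p under 0.01 were 20 and 27 between the siRNAs in NF and CAF, 867 and 29 for siHsp90aa1 and siHsp90ab1 across cell lines, 934 and 6 opposite to TGFb1, and 1450 for CAF against NF with TGFb1, and with the block 197, 179, 209 for siHsp90ab1 across cell lines and 82 for siHsp90ab1 opposite to TGFb1. Without 1 library the ranges were 157 to 329 and 44 to 102 for siHsp90ab1 in NF and CAF, 2460 to 4426 for siHsp90aa1 in CAF, 2478 to 4285 between the knockdowns in CAF, 453 to 951 and 0 to 2 for the differences, 2 to 9 lists for siHsp90ab1 in CAF, and for overlaps 21 to 58, 23 to 60, 34 to 73 and 8 to 43. The last, 29 with all libraries, was 8, 10 and 18 without NF siHsp90ab1 replicate 2, 1 and 3, 10, 12 and 15 without NF TGFb1 replicate 1, 2 and 3 and 18 without NF vehicle replicate 3. Of 459 values of named genes that passed, 3 were lost with RLE, 4 with upper quartile factors, 7 with voom, 7 with no filter, 43 with the compared groups alone and 0 with DESeq2, the other filter or the block, and 0 reversed in these 8 alternatives.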

Other observations

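The other strand of the duplex was tested only after the word picked for siHsp90ab1 was not found in its target, and the remaining tests were planned before their results were seen.

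Heat shock factor targets, the genes of the classical response to lost chaperone capacity, did not pass in camera with siHsp90aa1 and had small positive medians with siHsp90ab1. With siHsp90aa1 3 of 18 rose and 1 fell in NF (median -0.02, camera adjusted p = 0.754) and 1 rose and 2 fell in CAF (median -0.06, adjusted p = 0.471), with 4 falling in NF and 2 rising and 5 falling in CAF with the replicate block. With siHsp90ab1 the list passed in NF (median 0.10, adjusted p = 0.0281, 0.600 with an estimated correlation), and in CAF (median 0.08, adjusted p = 0.0696) with the replicate block alone (0.0304). With siHsp90aa1 Hsf2, a heat shock transcription factor gene, fell in both cell lines (-0.61 ± 0.13 in NF and -0.56 ± 0.13 in CAF, SE, n = 3 per group), and the small heat shock protein gene Cryab rose in NF (0.84 ± 0.20). Cholesterol synthesis genes had a median of 0.33 between CAF and NF with 10 of 20 higher and 2 lower (adjusted p = 0.220), and p53 targets one of 0.44 with 10 of 18 higher and 3 lower (adjusted p = 0.112), 5 lower with the replicate block.

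A hypothesis of off-target seed matches was tested over 14246 words of 7 bases in the 3' UTRs of 13061 genes. The word whose genes were lowest in NF was also the lowest in CAF for both pools (percent rank 0.00702), ACTGACG for siHsp90ab1 (322 genes) and TGGATAA for siHsp90aa1 (1114 genes). In the 3 comparisons without that siRNA the lowest percent rank was 3.26 for the first and 16.2 for the second. Of the genes that fell in both cell lines 33.3% held the word for siHsp90ab1 (15 of 45, among them Ppp1r14b, Ppard, Dag1 and Pdia6, against 3.22% in random sets) and 22.5% for siHsp90aa1 (224 of 996, among them Tgfbr1, Alcam, Bmper and Tmem151b, against 11.5%). These shares do not test the hypothesis, since each word was picked on the NF values that also select the genes. By the rank in CAF, part of the genes lowered by each pool may be seed effects (percent rank 0.00702).

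The target went weakly with the hypothesis for siHsp90aa1, since TGGATAA lies in 7 of 8 annotated Hsp90aa1 transcripts. These are forms of the same gene and count as a single match, and 15.4% of other genes' transcripts of similar length hold the word. In contrast, ACTGACG lies in 0 of 8 Hsp90ab1 transcripts, and the reverse complements lie in 0 of 8 for both, which argues against a match to the annotated target for siHsp90ab1. Genes with the word followed by A were not lower in CAF than genes with the word alone for siHsp90aa1 (0.0448 ± 0.0357, SE), which goes against it by little more than the SE, and the difference was -0.0279 ± 0.0422 for siHsp90ab1, which could not decide. In NF the mean was -0.149 with the A and -0.140 without for siHsp90aa1, and -0.189 and -0.0998 for siHsp90ab1, the direction that the hypothesis needs, with no SE computed.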
